A study of Homo sapiens with 4 samples.

How the data were processed

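Total RNA was extracted from BEAS-2B cells with Trizol and sequenced on the Illumina HiSeq platform, per the labels. The 4 libraries were 2 untreated and 2 treated with 100 µM formaldehyde for 48 h. The submitters' processing notes name FastQC 0.10.0, STAR 2.5.2 and Cufflinks 2.0.2 with the builds hg19 and GRCh37; trimming, treatment of multi-mapped reads and strand setting are not given in the sources used here. Each deposited file is a transcript annotation with the Cufflinks estimates of 1 library, and each file was matched to its sample by a name equal to the sample title. Its values are FPKM by the authors, per the file headers and attributes, with bounds of a confidence interval and a coverage value. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads shared by near-identical genes were assigned by the authors' software.

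Every file listed the same 40255 transcripts. The 894 transcripts with no gene name, 1.07% to 1.31% of a library's FPKM, were left out, and the FPKM of the others were summed for each of 23004 gene names. Coordinates are those of the files (hg19, 1-based, lowest start to highest end of the transcripts of a gene). No transcript of the mitochondrial chromosome was among those listed, so the list of mitochondrially encoded messenger RNAs was not analysed here.

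The deposited coverage was a constant multiple of FPKM in each library, the constant being mapped fragments times read length. The upper bound of the interval was FPKM times 1 plus 2 divided by the square root of the fragment number, so that fragment numbers of genes with 1 transcript could be recovered, and a regression of fragments over coverage on transcript length gave a read length of 51 nt. The depth was then 16.8, 26.5, 14.2 and 22.2 M fragments (M, mega) in untreated replicates 1 and 2 and formaldehyde replicates 1 and 2. These fragment numbers served to describe depth and the calls of short genes, and no count test was run. Genes listed at 0 numbered 5745 to 6594 per library.

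Genes with a mean FPKM of at least 1 over the 4 libraries (12407) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend), formaldehyde against untreated with no covariate, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. FPKM were not rescaled. Fold changes on this scale understate the change of low genes, and plain folds are ratios of mean FPKM. Gene lists with at least 5 tested members (29 of the 34 fixed) were tested with camera in limma with a preset correlation of 0.01 and, beside it, with a correlation estimated from the residuals, adjusted over the lists. Groups that do not overlap were counted as separated. The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined.

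Named genes were chosen by rule. They were the 12 largest increases and the 12 largest decreases in log2 fold change with adjusted p under 0.05, a mean of at least 5 FPKM in the higher group, groups that do not overlap, a longest transcript of at least 300 nt and a gene symbol. Where fewer passed, places were filled by the same rule with an unadjusted p under 0.05. Up to 4 members of each described list with the largest absolute moderated t were added, and ADH5, ALDH2, CHAF1A, CHAF1B, ASF1B, CDKN1A and HMOX1 in every case. Genes named outside the rule are said to be so. Not every list member chosen by the rule is named in the text, and the result for a gene is not reported here.

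The test was checked on simulated libraries with the means and spreads of the 4 real ones and 200 genes of 10 FPKM or more changed by a known fold. Over all genes it recovered 40.0% of the changed genes at 4-fold, 79.0% at 8-fold and 85.0% at 16-fold, and over genes of at least 300 nt 62.5%, 84.5% and 90.0%. The camera test called a simulated shifted list, and 1.50% of the unshifted lists fell under 0.05; the simulated genes were independent, unlike real ones. Alternatives covered the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), rescaling by median ratios, by the FPKM sum or by quantiles, genes of at least 300 nt, the highest transcript of each gene, eBayes without a trend or robust, the replicate number as a block, each library left out, a minimum change of 1.5 times, and for lists an estimated correlation and fry. The table of every list under every setting was added after seeing the data. Further settings added then were weights from the deposited bounds, genes of at least 300 nt combined with the block, with scaling or with a library left out, and for the lists no filter, FPKM-sum scaling, genes of at least 300 nt and the highest transcript of each gene. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15.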

Results

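RNA was sequenced from BEAS-2B cells, an immortalized line of human bronchial epithelium, that were left untreated or exposed to 100 µM formaldehyde for 48 h. Each group held 2 libraries. The protocol label gives the dose and the time, and the series title names the compound, a small aldehyde that crosslinks DNA and protein. The comparison asks which genes respond to formaldehyde, in a study whose title concerns chromatin assembly and cell transformation. The expression value is FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, as the authors deposited it, summed over the transcripts of a gene. The depth recovered from the deposited values was 16.8 and 26.5 M fragments (M, mega) in untreated replicates 1 and 2, and 14.2 and 22.2 M in formaldehyde replicates 1 and 2. At that depth a transcript of 2 kb at 10 FPKM carried a 95% counting error of 8.52% to 11.6%, which covers counting error only. Between 12049 and 12379 genes reached 1 FPKM in a library. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

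IFI27, an interferon-inducible gene on chromosome 14 (hg19, 94577079 to 94583033), rose from 16.1 ± 2.18 FPKM in untreated cells to 135 ± 0.184 FPKM with formaldehyde (mean ± SD, n = 2 each), 8.42-fold. Its log2 fold change was 3.003 ± 0.20 (SE, limma adjusted p = 0.0212), and it was the only gene with a transcript of at least 300 nt among the 19 past the threshold. The other 18, such as SNORD42A, SNORD87 and MIR1238 (chosen after their values were seen), are small RNA genes. For the 16 of them with a recoverable fragment number, no library held more than 3 fragments. SNORD42A, for example, was counted from 1 fragment in each untreated library and was listed at 0 in both formaldehyde libraries. Of 12407 genes tested on log2(FPKM + 1), a scale that understates the change of low genes, 10 rose and 9 fell in all, and 343 had an unadjusted p under 0.05, where chance alone gives 620. The 620 is not a fair yardstick here. A split by replicate number gave 2013 such genes, and a difference of that kind adds to the residual spread of the treatment test. With genes of at least 300 nt alone, 1 of 12015 genes passed, IFI27 (limma adjusted p = 0.0270), and 403 had an unadjusted p under 0.05. The call of IFI27 was lost with no filter on low values (limma adjusted p = 0.0921) and when any library was left out (limma adjusted p of 0.0809 to 0.135), with log2 fold changes of 2.87 to 3.13.

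The libraries did not group by treatment over all genes. Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.903 between the untreated libraries and 0.910 between the formaldehyde libraries. Across the groups it ran from 0.878 to 0.923. Both formaldehyde libraries lay above both untreated libraries in 16.2% of the genes and below them in 10.7%, where chance gives 16.7% each way. That share holds only where nothing else, such as replicate number, sets the libraries apart. An exact permutation test of 2 libraries against 2 cannot give a p under 0.333.

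Interferon-stimulated genes, the antiviral and antigen-presentation genes that interferon signalling switches on, were higher with formaldehyde as a group. Their median log2 fold change was 0.84 over 45 tested members, and 34 of them had both formaldehyde libraries above both untreated ones, with 0 the other way. ISG15, a ubiquitin-like protein, stood at 112 ± 16.2 FPKM untreated and 585 ± 195 FPKM with formaldehyde. IFI6 stood at 197 ± 29.0 and 748 ± 42.3 FPKM, OASL, a member of the oligoadenylate synthetase family, at 2.75 ± 0.332 and 11.2 ± 0.555 FPKM, and IFI44 at 2.13 ± 0.142 and 8.45 ± 0.401 FPKM (mean ± SD, n = 2 each). Over all genes tested, 1 member rose, IFI27, and adjusted over the list alone 20 rose and 0 fell. The list passed the camera test (adjusted p = 3.67e-29), and the test gave an adjusted p = 0.80 with an estimated correlation. The list's median was 0.71 in formaldehyde replicate 1 and 0.998 in replicate 2 against the untreated mean, and its call held without each library in turn. Leukocyte markers stayed low, at a median of 0 FPKM in formaldehyde replicate 1 and 0.0149 FPKM in replicate 2, although 2 of the 3 that reached the filter were higher (all chosen after their values were seen). CD68, which many cell types express, stood at 42.8 and 22.04 FPKM against 12.8 and 16.4 FPKM untreated, CORO1A, an actin-binding protein, at 4.75 and 4.02 against 1.53 and 2.69 FPKM, and the third, CD14, at 1.77 and 6.23 against 3.75 and 11.98 FPKM. LAPTM5, under the filter, was at 2.35 and 0.309 against 0.292 and 0.1299 FPKM.

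**Figure D1:**
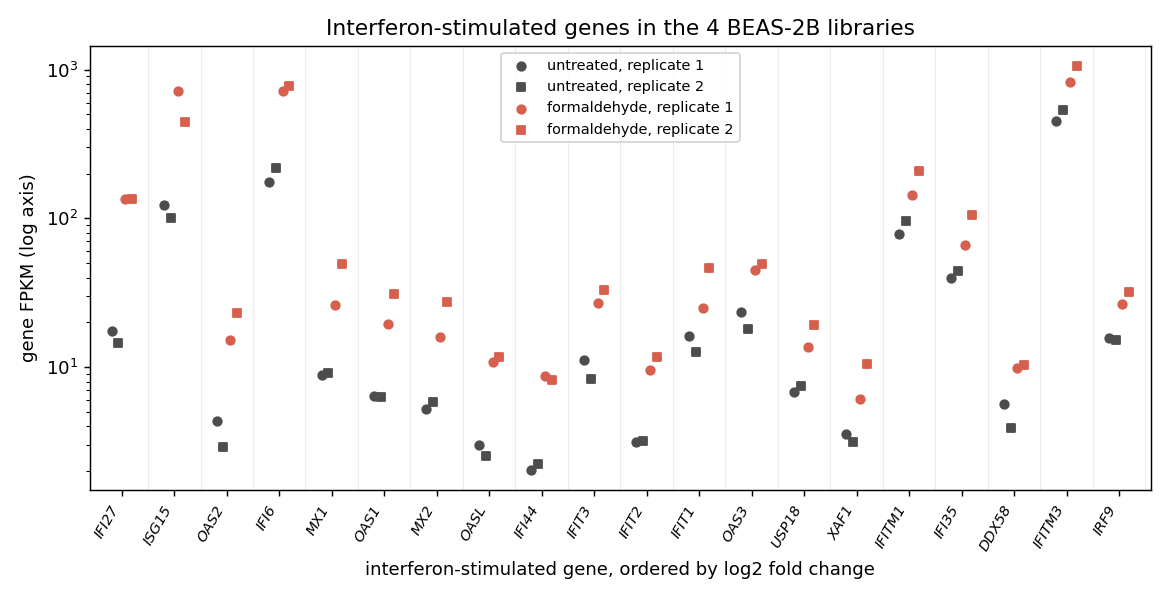
FPKM of the 20 interferon-stimulated genes that passed when adjusted over the list alone, on a log axis, with a point for each of the 4 libraries (grey untreated, red formaldehyde; circles replicate 1, squares replicate 2). Both formaldehyde libraries lie above both untreated libraries in each gene shown, with IFI27 at 136 and 135 FPKM against 17.6 and 14.5 FPKM.

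By the same test, 10 of the 29 gene lists fixed before the data were examined passed, 4 upward and 6 downward. None passed with an estimated correlation, where the smallest adjusted p was 0.80, and 0 passed by fry, a test of each list on its own (limma, 1 list at an unadjusted p under 0.05). The estimated correlation was 0.31 for interferon-stimulated genes, 0.56 for p53 target genes and 0.64 for mitosis and G2/M, beside the preset 0.01. With it the unadjusted camera p was 0.068, 0.291 and 0.330 in turn. The loss of calls does not rest on correlation alone. For NF-kB cytokines and chemokines the estimate was -0.018, under the preset, and the unadjusted camera p still rose from 0.094 to 0.202. With an estimated correlation, camera uses the few residual degrees of freedom of the 4 libraries, so a list could hardly pass. Failing it therefore does not tell whether a list changed. The preset form in turn takes members as nearly independent. The other splits of the 4 libraries into pairs, which follow no treatment, gave 9 and 15 lists by camera, so that the number of lists called does not set the treatment apart, while the interferon median in those splits was 0.16 (camera adjusted p = 0.0133, also past the threshold) and -0.16 (0.1298).

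The genes that the transcription factor ATF4 switches on under amino acid or translation stress were higher with formaldehyde. Over the 30 tested members the median log2 fold change was 0.40, 25 were higher and 5 lower, and 15 had both formaldehyde libraries above both untreated ones. TRIB3, a pseudokinase induced by ATF4, stood at 24.8 ± 4.20 FPKM untreated and 67.9 ± 0.568 FPKM with formaldehyde (mean ± SD, n = 2 each). STC2 stood at 46.9 ± 18.3 and 97.2 ± 11.8 FPKM, and PSAT1, an enzyme of serine synthesis, at 63.7 ± 10.5 and 107 ± 20.7 FPKM. No member passed over all genes, and adjusted over the list alone TRIB3 rose (limma adjusted p = 0.0360) and 0 fell. The list passed camera (adjusted p = 1.90e-07; adjusted p = 0.80 with an estimated correlation), and without untreated replicate 1 the call was lost (median 0.22, camera adjusted p = 0.259).

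Metallothioneins, small metal-binding proteins, had a median log2 fold change of 0.86, with 10 of 10 tested members higher and 6 separated between the groups. MT1G stood at 16.3 ± 3.76 FPKM untreated and 41.7 ± 13.9 FPKM with formaldehyde, and MT1H at 4.26 ± 0.984 and 9.81 ± 1.29 FPKM (mean ± SD, n = 2 each). No member passed, over all genes or adjusted over the list alone. The list passed camera (adjusted p = 1.29e-06; adjusted p = 0.80 with an estimated correlation), and its call held without each library in turn. Its members are near-identical neighbours on chromosome 16, and the authors' assignment of reads could split them unevenly. The median was 1.05 in formaldehyde replicate 1 and 0.57 in replicate 2 against the untreated mean, and 0.56 without untreated replicate 2. The list for intronic, nuclear or small RNA was also higher in formaldehyde replicate 1 (0.58) than in replicate 2 (-0.22).

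The p53 target genes, which answer to the transcription factor of the DNA damage response, were higher mainly in formaldehyde replicate 1. Their median stood 0.84 above the untreated mean in that library and 0.12 above it in replicate 2. CDKN1A, the p53-induced inhibitor of the cell cycle on chromosome 6 (hg19, 36644237 to 36655116), was at 31.8 and 48.9 FPKM untreated and at 355 and 49.5 FPKM in formaldehyde replicates 1 and 2. Its log2 fold change of 1.73 ± 0.94 (SE, limma adjusted p = 0.9999) became 0.32 without formaldehyde replicate 1. PLK3 was at 3.07 and 4.37 FPKM untreated and 11.9 and 7.65 FPKM with formaldehyde, and DDB2, a sensor of ultraviolet damage, at 8.94 and 10.4 against 22.2 and 13.9 FPKM. Over both libraries the median log2 fold change of the 29 tested members was 0.43, with 26 higher and 3 lower, and no member passed over all genes or adjusted over the list alone. The list passed camera (adjusted p = 1.51e-06; adjusted p = 0.80 with an estimated correlation), and the call was lost without formaldehyde replicate 1 (camera adjusted p = 0.657). The list for intronic, nuclear or small RNA in a library differed likewise, at 0.58 above the untreated mean in replicate 1 and at -0.22 in replicate 2.

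The lists for proliferation had lower medians with formaldehyde by small amounts, and most members did not separate the groups. The median log2 fold change was -0.25 over 42 genes of mitosis and the G2/M phase, of which 38 were lower, and -0.16 over 44 genes of DNA replication and S phase, of which 37 were lower. Both formaldehyde libraries lay below both untreated libraries in 15 and 7 of these genes in turn, and above them in 0 and 1. Over all genes the shares were 10.7% below and 16.2% above. MKI67, the gene of the proliferation marker Ki-67, stood at 52.7 ± 0.916 FPKM untreated and 36.1 ± 6.96 FPKM with formaldehyde, and NUSAP1, a spindle protein, at 119 ± 3.43 and 81.9 ± 18.6 FPKM. RRM2, a subunit of ribonucleotide reductase, stood at 73.0 ± 6.72 and 59.5 ± 3.56 FPKM (mean ± SD, n = 2 each). No member of either list passed over all genes or adjusted over the list alone. Both lists passed camera (adjusted p = 1.90e-07 for mitosis and 0.000341 for S phase; adjusted p = 0.80 and 0.81 with an estimated correlation). The mitosis median became 0.03 without untreated replicate 1 (camera adjusted p = 0.671). The S phase median became 0.00 without formaldehyde replicate 1 (camera adjusted p = 0.492), and without untreated replicate 1 its call was also lost (median -0.09, camera adjusted p = 0.159). The S phase median stood at -0.32 in formaldehyde replicate 1, where the list for intronic, nuclear or small RNA stood at 0.58, and at 0.0036 in replicate 2, where that list stood at -0.22.

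Histone genes were lower too. The median log2 fold change of the 24 tested genes of replication-dependent core histones, which are made in S phase to package new DNA, was -0.31, with 22 lower and 2 higher. In 10 of the 24, both formaldehyde libraries lay below both untreated ones, with 0 the other way. Of the 55 such genes found, the rest had a mean under 1 FPKM and were not tested. HIST2H2BE stood at 2.86 ± 1.27 FPKM untreated and 0.736 ± 0.376 FPKM with formaldehyde, and HIST1H2BH at 6.50 ± 3.75 and 2.37 ± 0.202 FPKM (mean ± SD, n = 2 each). No core histone passed, over all genes or adjusted over the list alone. The list passed camera (adjusted p = 9.13e-06; adjusted p = 0.80 with an estimated correlation), and its call held without each library in turn, with medians from -0.59 without untreated replicate 2 to -0.12 without untreated replicate 1. These genes are near-identical copies, so that reads could be split unevenly between them. Linker histones and histone variants had a median of -0.19 over 13 members, with HIST1H1C at 32.6 ± 8.26 and 18.5 ± 0.897 FPKM and H2AFX, the variant phosphorylated at DNA breaks, at 172 ± 2.29 and 123 ± 9.72 FPKM. In 3 of the 13, both formaldehyde libraries lay below both untreated ones, with 1 the other way. No member passed over all genes or adjusted over the list alone. That list passed camera (adjusted p = 0.0309; adjusted p = 0.80 with an estimated correlation), and the call was lost without untreated replicate 1 (median -0.12, camera adjusted p = 0.224), without formaldehyde replicate 1 (median -0.12, camera adjusted p = 0.347) and with the highest transcript of each gene (median -0.17, camera adjusted p = 0.131).

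Chromatin assembly factors and histone chaperones, the machinery that places histones on DNA, did not pass as a list. The list's median was -0.12 in formaldehyde replicate 1 and 0.11 in replicate 2 against the untreated mean. Over the 37 tested members the median log2 fold change was 0.00, with 19 higher and 18 lower (camera adjusted p = 0.630, direction down against the mean of 0.01), and no member passed over all genes or adjusted over the list alone. CHAF1A, the large subunit of chromatin assembly factor 1 (chromosome 19, hg19, 4402660 to 4443394), stood at 64.2 ± 25.4 FPKM untreated and 55.8 ± 24.3 FPKM with formaldehyde, a log2 fold change of -0.21 ± 0.43. CHAF1B (chromosome 21, 37757689 to 37789125) stood at 43.8 ± 5.13 and 43.3 ± 17.5 FPKM, a log2 fold change of -0.07 ± 0.33. ASF1B (chromosome 19, 14230321 to 14247440), a chaperone of histones H3 and H4, stood at 98.1 ± 6.51 and 78.9 ± 10.3 FPKM, a log2 fold change of -0.32 ± 0.22 (mean ± SD in FPKM, n = 2 each; SE on the log2 scale; limma adjusted p = 0.9999 for each). The sign for CHAF1A and CHAF1B turned when untreated replicate 2 (0.20 and 0.04) or formaldehyde replicate 1 (0.24 and 0.34) was left out.

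Genes that handle formaldehyde or repair its lesions did not pass either. The median log2 fold change was 0.08 over 19 genes of formaldehyde detoxification and one-carbon metabolism (camera adjusted p = 0.630) and -0.09 over 33 genes of Fanconi anemia and crosslink repair (camera adjusted p = 0.0649), and no member of either list passed over all genes or adjusted over the list alone. The detoxification median was 0.23 without untreated replicate 1 and 0.0012 without untreated replicate 2. ADH5, the dehydrogenase that oxidizes glutathione-bound formaldehyde (chromosome 4, hg19, 99992130 to 100009931), stood at 21.8 ± 12.2 FPKM untreated and 18.6 ± 4.76 FPKM with formaldehyde, a log2 fold change of -0.12 ± 0.44. It was 0.45 without untreated replicate 1 and 0.13 without formaldehyde replicate 2. ALDH2, the mitochondrial aldehyde dehydrogenase (chromosome 12, 112204691 to 112247789), stood at 11.9 ± 2.15 and 14.5 ± 2.25 FPKM, a log2 fold change of 0.26 ± 0.23. FANCD2, the protein ubiquitinated at crosslinks, stood at 14.7 ± 0.382 and 10.9 ± 0.191 FPKM, and MTHFD1L, a mitochondrial enzyme of folate metabolism, at 25.9 ± 1.58 and 37.3 ± 3.31 FPKM. HMOX1, the heme oxygenase of the oxidative stress response (chromosome 22, 35777060 to 35790207), stood at 14.9 ± 4.24 and 13.8 ± 1.61 FPKM, a log2 fold change of -0.08 ± 0.26 (mean ± SD in FPKM, n = 2 each; SE on the log2 scale; limma adjusted p = 0.9999 for each gene named). It was 0.20 without untreated replicate 2 and 0.03 without formaldehyde replicate 1. The Fanconi list passed with a mean FPKM of at least 5, median-ratio or FPKM-sum scaling, or the highest transcript of each gene (camera adjusted p of 0.0368 to 0.0456). The estimated correlation was run only over all libraries with none of these changes, where camera gave an adjusted p = 0.80. The median of the Fanconi list was -0.14 without untreated replicate 2, 0.0069 without untreated replicate 1 and 0.0091 without formaldehyde replicate 2.

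Of 26 tested NF-kB cytokines and chemokines, 17 were higher and 9 lower, at a median log2 fold change of 0.20 (camera adjusted p = 0.181). By fry the list had an unadjusted p = 0.0388 and an adjusted p = 0.733. None passed over all genes, and adjusted over the list alone 3 rose, IL1B, CSF2 and IL11, and 0 fell. IL1B, the gene of interleukin-1 beta, stood at 18.6 ± 2.77 FPKM untreated and 53.3 ± 3.93 FPKM with formaldehyde, and CSF2, the growth factor of granulocytes and macrophages, at 13.3 ± 2.67 and 68.5 ± 27.1 FPKM. CXCL6, a neutrophil chemokine, was lower, at 7.13 ± 2.42 and 2.43 ± 0.979 FPKM (mean ± SD, n = 2 each), and did not pass.

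Cholesterol synthesis and TGF-beta target genes had lower medians as lists, and most members did not separate the groups. Over 25 genes of cholesterol biosynthesis the median log2 fold change was -0.23, with 23 lower. In 9 of them both formaldehyde libraries lay below both untreated ones, with 0 the other way. SREBF2, the transcription factor of the pathway, stood at 65.9 ± 9.51 FPKM untreated and 46.2 ± 11.7 FPKM with formaldehyde, and INSIG1 at 37.3 and 32.9 against 7.44 and 28.8 FPKM, low in formaldehyde replicate 1. The median of the 27 tested TGF-beta target genes was -0.20, with 19 lower and 8 higher. In 7 of them both formaldehyde libraries lay below both untreated ones, with 4 the other way. TGFB2 stood at 19.6 ± 6.26 and 8.78 ± 1.71 FPKM, and SMAD6, an inhibitor of the related BMP signal, at 7.96 ± 2.08 and 3.21 ± 1.44 FPKM (mean ± SD, n = 2 each). No member of either list passed over all genes or adjusted over the list alone. Both passed camera (adjusted p = 5.67e-05 for cholesterol and 0.00526 for TGF-beta; adjusted p = 0.80 for each with an estimated correlation). The cholesterol call was lost without untreated replicate 1 (median -0.06, camera adjusted p = 0.320) or formaldehyde replicate 1 (median -0.10, camera adjusted p = 0.111), and the TGF-beta call without untreated replicate 2 (median 0.04, camera adjusted p = 0.912) or formaldehyde replicate 2 (median -0.14, camera adjusted p = 0.503).

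Regardless of list membership, the 12 largest increases by the rule for named genes were IFI27, CCND1, G0S2, ISG15, IL11, CSF2, OAS2, ANGPTL4, TGM2, ETV4, IFI6 and MX1, of which IFI27 passed over all genes and the other 11 did not (limma adjusted p of 0.0845 or more). CCND1, the gene of cyclin D1, was at 14.6 and 3.67 FPKM untreated and 129 and 34.7 FPKM with formaldehyde, a log2 fold change of 2.998 ± 0.83. ETV4, an ETS transcription factor, stood at 4.52 ± 0.40 and 21.3 ± 1.73 FPKM, a log2 fold change of 2.01 ± 0.20 (limma adjusted p = 0.0845), and passed with a robust variance trend (limma adjusted p = 0.0396). G0S2, an inhibitor of lipolysis, stood at 26.4 ± 1.03 and 153 ± 83.4 FPKM, and TGM2, a transglutaminase, at 1.65 ± 0.474 and 9.90 ± 3.30 FPKM. The 12 largest decreases, none of which passed (limma adjusted p = 0.9999 for each), were SULF1, CADM3, PDZK1IP1, CDKN2B, DUSP2, CCDC80, SAMD11, HTRA1, ID2, CXCL6, ATOH8 and MUC1. CDKN2B, an inhibitor of the cyclin D kinases, stood at 30.5 ± 3.12 FPKM untreated and 11.5 ± 7.79 FPKM with formaldehyde, HTRA1, a secreted protease, at 9.91 ± 2.86 and 3.45 ± 0.522 FPKM, and ID2, an inhibitor of helix-loop-helix factors, at 6.71 ± 2.26 and 2.197 ± 0.363 FPKM (mean ± SD, n = 2 each).

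**Figure D2:**
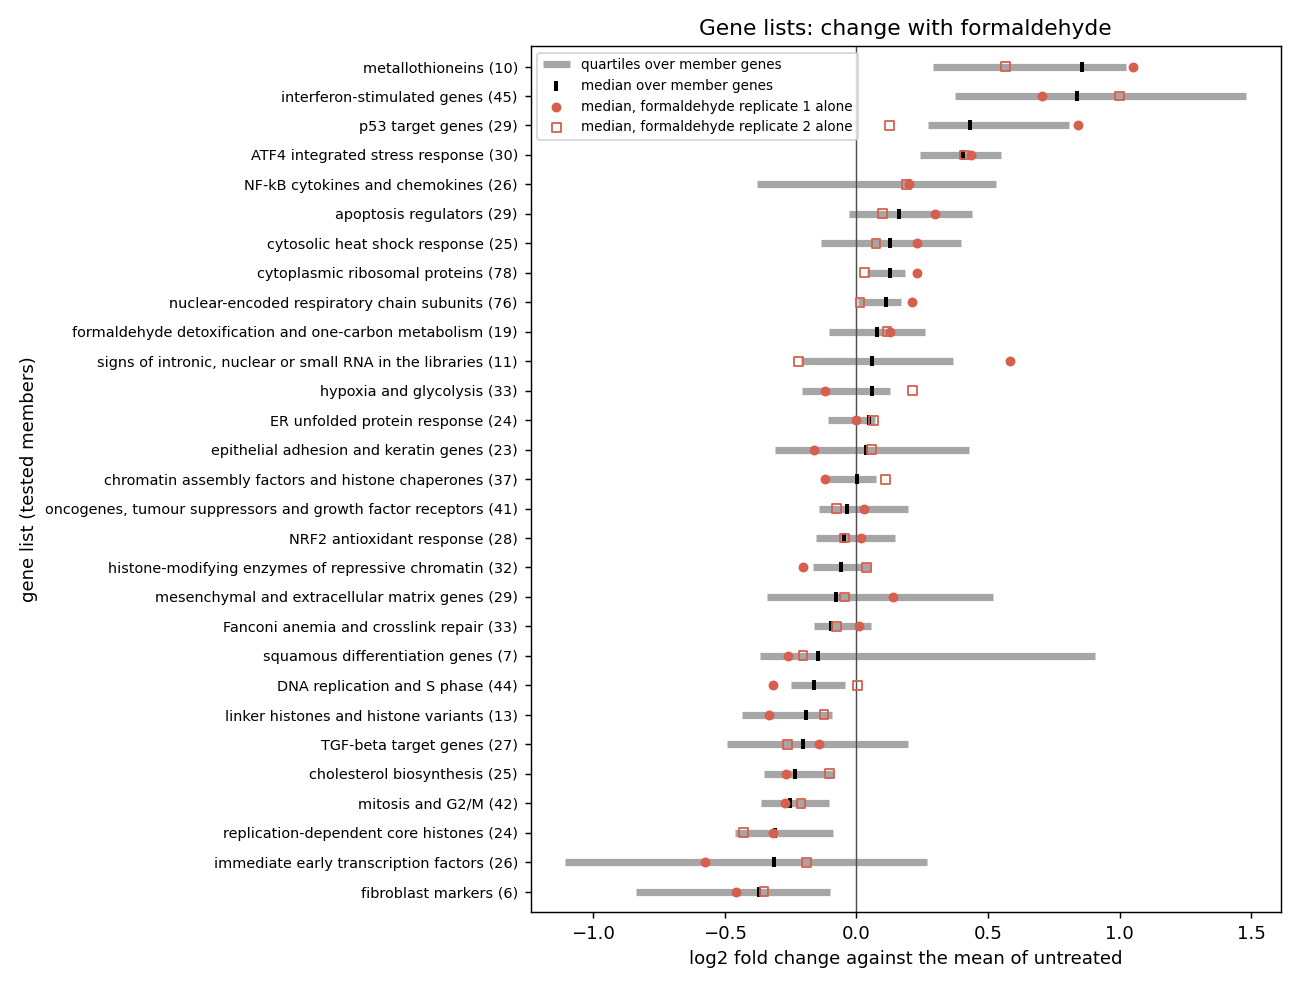
Log2 fold change against the mean of the untreated libraries, on the log2(FPKM + 1) scale, for the 29 tested lists, with the number of tested members in brackets; black marks are medians over members for the 2 formaldehyde libraries together, grey bars their quartiles, and red symbols the medians of each formaldehyde library alone. The interferon list lies at 0.71 and 0.998 in the formaldehyde libraries, and the p53 list at 0.84 and 0.12.

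The remaining lists did not pass camera. The medians were 0.16 for apoptosis regulators (camera adjusted p = 0.0649), 0.13 for the cytosolic heat shock response (0.280), 0.13 for cytoplasmic ribosomal proteins (0.183), 0.11 for nuclear-encoded respiratory chain subunits (0.263), -0.05 for the NRF2 antioxidant response (0.280) and -0.06 for histone-modifying enzymes of repressive chromatin (0.103). Growth-related oncogenes, tumour suppressors and growth factor receptors had a median of -0.03 and a mean of 0.06 (camera adjusted p = 0.662). Median and direction of the test differed in sign for the unfolded protein response of the endoplasmic reticulum (median 0.05, mean 0.00, test down), hypoxia and glycolysis (median 0.06, mean 0.03, test down) and squamous differentiation (median -0.15, mean 0.27, test up), with camera adjusted p = 0.898 for each. The list for intronic, nuclear or small RNA had a median of 0.06 over both formaldehyde libraries (camera adjusted p = 0.898), -0.22 without formaldehyde replicate 1 (0.00497) and 0.58 without formaldehyde replicate 2 (0.00990), with adjusted p = 0.96 with an estimated correlation over all libraries. Markers of fibroblasts had a median of -0.37 over the 6 tested of 15 members (camera adjusted p = 0.0649), COL1A1 (chosen after its values were seen) being at 279 and 568 FPKM untreated and 137 and 254 FPKM with formaldehyde. That list passed with no filter on low values (camera adjusted p = 0.000869), genes of at least 300 nt (0.0337) and weights from the deposited bounds (0.0210). Over all libraries with none of these changes, camera gave it an adjusted p = 0.80 with an estimated correlation. Its median was -0.69 without untreated replicate 1, -0.46 without formaldehyde replicate 2 and -0.04 without untreated replicate 2.

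Calls of other lists also hung on the setting. For the lists, no filter, FPKM-sum scaling, genes of at least 300 nt, the highest transcript of each gene and weights from the deposited bounds were settings chosen after seeing the data. Apoptosis regulators passed with genes of at least 300 nt, no filter, a mean FPKM of at least 5, median-ratio or FPKM-sum scaling, the highest transcript of each gene, or weights from the deposited bounds (camera adjusted p under 0.05 for each). Over all libraries with none of these changes, camera gave them an adjusted p = 0.80 with an estimated correlation. Their median was 0.40 without untreated replicate 1, 0.30 without formaldehyde replicate 2 and -0.02 without untreated replicate 2. Cytoplasmic ribosomal proteins had a median of 0.32 without untreated replicate 1 (camera adjusted p = 0.000727) and -0.10 without untreated replicate 2 (0.126), with adjusted p = 0.96 with an estimated correlation over all libraries. Nuclear-encoded respiratory chain subunits passed in opposite directions, at 0.34 without untreated replicate 1 (camera adjusted p = 0.000223) and -0.14 without untreated replicate 2 (0.0340), and passed at 0.21 without formaldehyde replicate 2 (0.0403). Over all libraries it had an adjusted p = 0.96 with an estimated correlation. Without untreated replicate 2 the NRF2 antioxidant response (median -0.16, camera adjusted p = 0.0370) and the unfolded protein response (0.16, 0.0475) passed, and without formaldehyde replicate 2 the histone-modifying enzymes of repressive chromatin (-0.20, 0.0233). Over all libraries these had adjusted p = 0.92, 0.96 and 0.92 with an estimated correlation. Too few markers of airway secretory and ciliated cells (2 tested), leukocytes (3), endothelium (1) and erythroid cells (0) reached the filter for a test.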

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

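Weights from the deposited bounds, the combined settings with genes of at least 300 nt and, for the lists, no filter, FPKM-sum scaling, genes of at least 300 nt and the highest transcript of each gene were chosen after the result was seen; the others were fixed before the data were examined. The genes changed by formaldehyde, 19 in all, became 0 with no filter on low values (limma; 652 of 18317 genes at an unadjusted p under 0.05), 1 with genes of at least 300 nt, also with median-ratio scaling (1), and 3 with weights from the deposited bounds. With 1 library left out they numbered 31 to 55 (31 without untreated replicate 2, 44 without formaldehyde replicate 1, 55 without untreated replicate 1 and 55 without formaldehyde replicate 2), of which 10 to 13 were among the 19; the lone library was assumed to vary like the other group. The other settings without a block gave 17 to 24. Among genes of at least 300 nt, 35 passed leaving untreated replicate 1 aside, 15 leaving untreated replicate 2 aside, 27 leaving formaldehyde replicate 1 aside and 165 leaving formaldehyde replicate 2 aside, with 4 to 12 interferon-stimulated genes among them; the cause was not tested. IFI27 passed in each of these 4, and kept its direction in every setting run. Among these genes the prior degrees of freedom were 5.25 with all 4 libraries. They were 11.1 and 11.6 leaving untreated replicates 1 and 2 aside in turn, and not finite leaving formaldehyde replicate 1 or 2 aside. Where they were not finite, every gene took the shared variance, so those calls do not rest on the spread of each gene. More calls with a library left aside are therefore not added support. The number of lists, 10, became 0 with an estimated correlation and 0 by fry, and was 7 to 15 with 1 library left out and 10 to 12 in the other settings that change 1 choice. Among genes of at least 300 nt it was 9 to 18 leaving a library aside and 12 with median-ratio scaling.

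With the replicate number as a replicate block, 29 genes passed, and 497 among genes of at least 300 nt, including all 24 genes named by size, and 12 lists passed (14 among genes of at least 300 nt), the 10 of the fit without a block with apoptosis regulators and fibroblast markers (camera adjusted p = 0.0469 for each; adjusted p = 0.80 with an estimated correlation and no block). In the block fit of genes of at least 300 nt the prior degrees of freedom were not finite either. Every gene took the shared variance, so the 497 calls do not rest on the spread of each gene. Over all genes the block added ETV4 (limma adjusted p = 0.0297), CCND1 (0.00773) and CSF2 (0.0395) to IFI27 among the genes named by size. No label says that the numbers mark a shared culture or day, and 2 pairs are too few to show it. The differences between replicates 1 and 2 correlated across genes between the groups at r = 0.25 (0.50 for genes of at least 300 nt). Depth followed replicate number too. Replicate 2 was deeper than replicate 1 in both groups, at 26.5 against 16.8 M fragments untreated and 22.2 against 14.2 M with formaldehyde. Splitting the libraries by replicate number instead of treatment gave 24 genes (limma) and 2013 at an unadjusted p under 0.05 against 343 for treatment. The last split gave 3 genes and 90. Replicate number thus set the libraries apart in more genes than treatment did. The counts are tied, since a difference in 1 split adds to the residual spread of the others, so they do not show what sets the libraries apart.

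Among named genes, with each library left out in turn, the direction turned for ADH5 (-0.70 to 0.45; 0.13 without formaldehyde replicate 2), CHAF1A (-0.66 to 0.24; 0.20 without untreated replicate 2), CHAF1B (-0.49 to 0.34; 0.04 without untreated replicate 2), HMOX1 (-0.36 to 0.20; 0.03 without formaldehyde replicate 1) and H2AFV (-0.87 to 0.0038). The highest came without untreated replicate 1 for ADH5 and H2AFV, formaldehyde replicate 1 for CHAF1A and CHAF1B, and untreated replicate 2 for HMOX1. Of the 10 lists that passed, it turned for the medians of 3, mitosis and G2/M (-0.50 to 0.0296, the latter without untreated replicate 1), DNA replication and S phase (-0.32 to 0.0036, without formaldehyde replicate 1) and TGF-beta target genes (-0.27 to 0.0369, without untreated replicate 2), and of the 19 lists that did not pass, for the medians of 16. That of LAMB3 turned with the highest transcript of each gene (-0.12). The cause was not tested. At the depth of the shallowest library, 14.2 M fragments (M, mega), a transcript of 2 kb at 1 FPKM carried a 95% counting error of 36.7%.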

Other observations

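The list of immediate early transcription factors, which respond to serum and growth factors within minutes, stood highest in untreated replicate 2 by its median. Not every member did: the list also holds phosphatases, and DUSP4 and DUSP6 were highest in formaldehyde replicate 1 (7.19 and 6.72 FPKM). DUSP2 was highest in untreated replicate 2 (10.7 FPKM). EGR1 was at 600 FPKM in untreated replicate 2 and at 6.65, 9.59 and 25.2 FPKM in untreated replicate 1 and formaldehyde replicates 1 and 2, and FOS was at 162 FPKM against 0.731, 1.55 and 1.70 FPKM (both chosen after their values were seen). The median log2 fold change of the 26 tested members was -0.31 with formaldehyde (camera adjusted p = 0.627). The list passed in opposite directions at -1.17 without untreated replicate 1 (camera adjusted p = 1.39e-13) and 0.88 without untreated replicate 2 (3.08e-13), and had an adjusted p = 0.96 with an estimated correlation over all libraries. FOSL1, a member of the AP-1 family, was separated between the groups, at 37.1 ± 7.38 FPKM untreated and 129 ± 32.9 FPKM with formaldehyde (mean ± SD, n = 2 each). It passed adjusted over the list alone (1 rose, 0 fell), and no member passed over all genes.

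Of 23 tested genes of epithelial adhesion and keratins, 13 were higher and 10 lower with formaldehyde, at a median log2 fold change of 0.04 (camera adjusted p = 0.530), and the list passed without untreated replicate 2 (median 0.17, camera adjusted p = 0.00185; adjusted p = 0.92 with an estimated correlation over all libraries). KRT7, a keratin of simple epithelium, stood at 166 ± 36.2 FPKM untreated and 425 ± 150 FPKM with formaldehyde, KRT18 at 216 ± 13.5 and 388 ± 42.1 FPKM, and DSP, the gene of desmoplakin, at 2.81 ± 0.318 and 6.05 ± 0.229 FPKM. Of 29 mesenchymal and extracellular matrix genes, 13 were higher and 16 lower, at a median of -0.08 and a mean of 0.08 (camera adjusted p = 0.898, direction down). TNC, the gene of tenascin C, stood at 20.02 ± 0.128 and 12.4 ± 0.445 FPKM, and CD44, the hyaluronan receptor, at 48.0 ± 6.21 and 95.8 ± 23.2 FPKM (mean ± SD, n = 2 each). No member of either list passed over all genes or adjusted over the list alone.

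All tests of explanations below were chosen after the results were seen. The first pattern is the higher level of interferon-stimulated genes in both formaldehyde libraries. RNA from leukocytes is argued against as the whole cause, since the median of the 21 leukocyte markers was at most 0.0149 FPKM in a formaldehyde library, with PTPRC, the gene of CD45 (chosen after its values were seen), at 0.00 and 0.00969 FPKM. Scaling is argued against as the whole cause, since the lowest list median over 3 scalings was 0.79, beside 0.84 as deposited. A difference between the cultures other than formaldehyde stays open, because 2 libraries against 2 allow 3 splits, too few for a share under 0.05; the real median was 0.84 and the largest in the other splits 0.163 in size, and the list passed camera in 1 of those splits (adjusted p = 0.0133). An interferon response to formaldehyde remains a hypothesis.

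The second pattern is that 27 of 29 p53 target genes were higher in formaldehyde replicate 1 than in replicate 2, by a median of 0.87 on the log2 scale. Scaling of that library is argued against, since the median difference was 0.89 after median-ratio scaling. The RNA quality of that library stays open: the list for intronic, nuclear or small RNA differed by 0.76 in the same direction, and 1 library cannot separate these lists. That difference was not shared by all its members (those named here chosen after their values were seen). RMRP was at 56.9 and 4.33 FPKM in formaldehyde replicates 1 and 2, and RPPH1 at 11.7 and 0.976 FPKM. MALAT1 was at 38.7 and 38.5 FPKM, and TUG1 at 22.5 and 24.3 FPKM. SNHG5 was at 36.9 and 13.7 FPKM, SNHG8 at 55.68 and 17.998 FPKM, and GAS5 at 104.8 and 55.96 FPKM. These were also higher in untreated replicate 1 than in 2, at 24.1 against 11.2, 37.1 against 13.9 and 55.1 against 38.4 FPKM. SNHG1, SNHG12, MALAT1 and NEAT1 were lower in untreated replicate 1 than in 2. The difference in SNHG5, SNHG8 and GAS5 thus went with replicate number, and need not mark the RNA quality of formaldehyde replicate 1. No biological explanation was tested, as no label separates these libraries.

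The third pattern is that 18 of the 19 genes past the threshold are under 300 nt. Sampling of a few fragments is a candidate explanation, as the highest number behind any of the 16 genes with a recoverable number was 3, and 15 of the 18 were listed at 0 in both libraries of a group. The other splits of the libraries gave 23 and 3 such genes. No biological explanation was tested.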
